A study of Mus musculus with 25 samples.

How the data were processed

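The series holds 25 samples of mouse immune cells. The 19 ChIP-seq samples were not analysed here. The 6 remaining samples are H3K27ac HiChIP libraries of splenic CD8+ T cells of strain C57BL/6J, which were activated for 2 days and rested for 4 h before control treatment or IL-2, per the labels' protocols. HiChIP joins DNA ends that lie close together in the nucleus, enriches the joined fragments with an antibody, here against the active chromatin mark H3K27ac, and counts read pairs between genome bins. The 6 libraries cover 3 genotypes (wild type, WT; a deletion in an Il2ra intron; a deletion upstream of Il2ra) and 2 treatments, with 1 library per genotype and treatment. The deposited tables are numbered as replicate 2 in their names, while the labels give no replicate number; whether a first replicate exists is not given in the sources used here. The labels name no separate animals or cultures, and no genotype and treatment has a second library here. P-values thus measure no spread between like libraries. Their spread comes from how the IL-2 change differs between genotypes, pooled over features, and may be technical. The coordinates of the deletions and the IL-2 dose and duration for these libraries are not given in the sources used here.

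Reads were processed with CASAVA, Bowtie2 2.2.6 and HiC-Pro against mm10 (GRCm38), per the submitters' processing notes. The deposited tables are in the layout of the loop caller FitHiChIP, with 1 kb bins, per the file headers; its version and the peak set it used are not given in the sources used here. Each row gives a pair of bins, the deposited contact count of the pair, and the deposited coverage of each bin, a whole-number count of reads. Tests on the tables found no pair with fewer than 20 contacts and none closer than 5 kb, and the deposited p-value and q-value columns were empty. Whether the tables hold every such pair or pairs that passed a threshold of the loop caller is not given in the sources used here. A pair that is not listed has at most 19 contacts, an anchor outside the authors' peaks or, if a threshold was applied, possibly 20 or more contacts. It was treated as below the listing limit, not as 0. Deposited bias factors reached 2.07e+53 and were not used here. The contact counts and coverage had not been normalised.

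Loops were pairs of bins, matched on both bins exactly. The libraries listed 121571 loops in all, of which 28033 were listed in each of the 6 libraries (shared loops). The shared loops and the 18580 bins that anchored a listed loop in all 6 libraries (shared bins) were the features tested. Of the shared bins, 15.4% held a gene end, 53.3% lay elsewhere inside a gene and 31.3% lay in no protein-coding gene. Genes were taken from the RefSeq annotation of GRCm38.p6, the build of the files. That table gives no strand, exons or transcripts, so promoter contacts were counted at gene ends: the contacts of all shared loops with an anchor in a bin that held either annotated end of the gene. Of 72 genes whose strand is textbook knowledge, the start of transcription had the larger coverage in 47, the other end in 7, and neither end was listed in 18. The start of Il2ra was taken from background knowledge. Of 21887 protein-coding genes, 2820 had gene-end contacts, in 2489 features, since genes that share their bins share a value and are named together.

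Contact counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM scaling, R 4.3.3), with genotype and treatment as additive terms over all 6 libraries, which leaves 2 residual degrees of freedom. This fit assumes that IL-2 has the same effect in every genotype; a further fit tested the IL-2 response of 1 genotype against that of the other 2 and was chosen after seeing the data. That fit leaves 1 residual degree of freedom, from the gap between the responses of the 2 other genotypes. The response set apart has no spread of its own. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and every adjusted p of a loop or gene comes from edgeR unless another tool is named. Errors of log2 fold changes are standard errors (SE). The common dispersion was 0.00264 for loops and 0.00212 for gene ends. For loops the prior degrees of freedom were infinite, so loop p-values rest on a spread pooled over all loops, not on each loop's own. The 14 gene lists were fixed before the data were examined, and all 181 of their genes matched the annotation. The 9 lists with at least 3 measured members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. The other 5 lists, markers of CD4+ or regulatory T cells, NK cells, B cells, myeloid cells and erythroid cells, had too few measured members.

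Named genes followed a rule fixed before the data were examined: up to 10 of the largest rises and 10 of the largest falls among genes past the threshold that moved the same way in each genotype or treatment, the measured Il2ra locus genes, and the 2 members of each tested list with the smallest p in the IL-2 comparison. For loops the rule took 5 rises and 5 falls, and the 10 loops of the Il2ra promoter bin with the highest mean contact count over the libraries that listed them. Other list members that passed the test, genes singled out of the further fit and the regions drawn around Il2ra were chosen after their values were seen. Some genes and loops that the rule or the lists would name are not reported here by name.

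Contacts of the Il2ra promoter bin were compared between single libraries as ratios of summed contacts scaled by the TMM factors of the shared loops, with exact binomial intervals at 95%. Intervals of contact counts are exact Poisson intervals. Read pairs carry no molecular identifiers in these tables, so all intervals cover counting error only. These sums depend on how many pairs reached the listing limit. Each ratio is therefore given with the ratio over pairs listed in both libraries and with the ratios obtained by setting unlisted pairs to 0 or to 19 contacts. These are not limits where an anchor lay outside the authors' peaks or where a further threshold had removed pairs.

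The listed contacts summed to between 1314137 in the control library of the intron deletion and 3596995 in the IL-2 library of WT. Of pairs listed elsewhere with an expected count of 20 to 30 in a library, 23.3% were unlisted there, against 0.0168% of those expected at 60 or more. Counts with known changes were simulated for 28033 loops. A change of fold 2 was set in 66 loops per comparison. It was called for 83.3% of them in the IL-2 comparison, 59.1% in the intron deletion and 62.1% in the upstream deletion. At fold 1.5 these shares were 32.8%, 13.4% and 11.9%, and at fold 1.25 they were 2.99%, 0% and 0%, of 67 changed loops each. For gene ends, with 2489 features tested, the shares at fold 2 were 98.5%, 95.5% and 92.4% of 66 changed features. At fold 1.25 they were 43.3%, 35.8% and 25.4% of 67. Between 0 and 8 unchanged features were called. In a run that kept only loops with at least 20 simulated contacts in every library, fold 2 was called for 91.5%, 75% and 71.4%. These are shares of 47, 44 and 42 changed loops. The simulations used 1 dispersion and the same IL-2 effect in every genotype, so these shares need not hold for the data. A list shifted on purpose reached an adjusted p of 4.16e-32, with 0 of the other lists called among 9 tested.

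Alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, a mean of at least 50 contacts, the upper part of the loops by contact count, scaling by 9 distance classes, loops listed in at least 3 libraries with unlisted pairs as 0, leaving out each library, and dropping the other term of the model. For the IL-2 comparison, leaving out either library of a genotype leaves its other library fitted exactly. Both fits then rest on the other genotypes alone and are not separate checks. Added after seeing the data were scaling by the summed coverage of the shared bins, leaving out both intron deletion libraries, loops anywhere in the gene span, the coverage of gene-end bins or of the Il2ra promoter bin, and Il2ra promoter pairs outside the near-empty stretch of the deletion genotype. Tables were handled with the data.table package, version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.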

Results

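The data were contacts between 1 kb bins of the mouse genome that carry the active chromatin mark H3K27ac, measured by HiChIP in splenic CD8+ T cells. The cells had been activated for 2 days and rested for 4 h, and were then left as controls or given IL-2, the cytokine whose receptor alpha chain (CD25) is encoded by Il2ra. There were 3 genotypes, wild type (WT), a deletion in an intron of Il2ra (intron deletion) and a deletion upstream of Il2ra (upstream deletion). Each genotype and treatment had 1 library, which gave 3 libraries per treatment and 2 per genotype. The deposited tables listed 72698 loops in the control and 94922 in the IL-2 library of WT, 38879 and 72743 for the intron deletion, and 56113 and 61168 for the upstream deletion. Their contacts summed to 2619773 and 3596995 in WT, 1314137 and 2709959 in the intron deletion, and 1965388 and 2203507 in the upstream deletion. The median loop held 28 to 30 contacts in each library, close to the minimum of 20 at which loops were listed, so that which loops appear in a table depended on depth.

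Loops listed in both libraries of a pair, as a share of those listed in either, were compared first. Control and IL-2 libraries shared 0.591 of their loops in WT (62229 loops), 0.495 in the intron deletion (36958) and 0.585 in the upstream deletion (43271). Against WT, the intron deletion shared 0.443 in control (34246 loops) and 0.527 with IL-2 (57848), and the upstream deletion 0.597 (48158) and 0.564 (56302). With partners allowed within 1 bin these shares were between 0.675 and 0.827. Restricted to the 38879 loops with the most contacts in each library, the share for control and IL-2 libraries of the intron deletion was 0.646. None of these shares has a replicate check.

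The first comparison asked which parts of the Il2ra locus contact the Il2ra promoter in WT and mutant cells. Il2ra (gene ID 16184) lies on chromosome 2 from 11642792 to 11693194 (mm10), and its promoter was the bin from 11642001 to 11643000. The labels give no coordinates for the deletions, so the libraries were inspected around the gene. The 22 bins from 11645001 to 11667000, in the 5' part of the gene body, included 17 listed bins in the control and 21 in the IL-2 library of WT, 16 and 18 in the upstream deletion, and 1 in each library of the intron deletion. The 23 bins from 11609001 to 11632000, between Rbm17 and Il2ra, included 16 and 18 listed bins in WT, 4 and 13 in the intron deletion, and 1 and 2 in the upstream deletion. Each deletion genotype thus had its near-empty stretch on the side of the promoter that its label names. Whether these stretches are the deletions was not tested. Their listed bins held reads. In the intron deletion these were 467 at 11647001 in control and 1300 at 11645001 with IL-2. In the upstream deletion they were 254 at 11631001 in control, and 647 at 11616001 and 349 at 11631001 with IL-2. The stretches as drawn were thus not missing throughout. A deleted segment would give no reads, so the missing contacts inside these stretches need not be a change in chromatin.

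**Figure D1:**
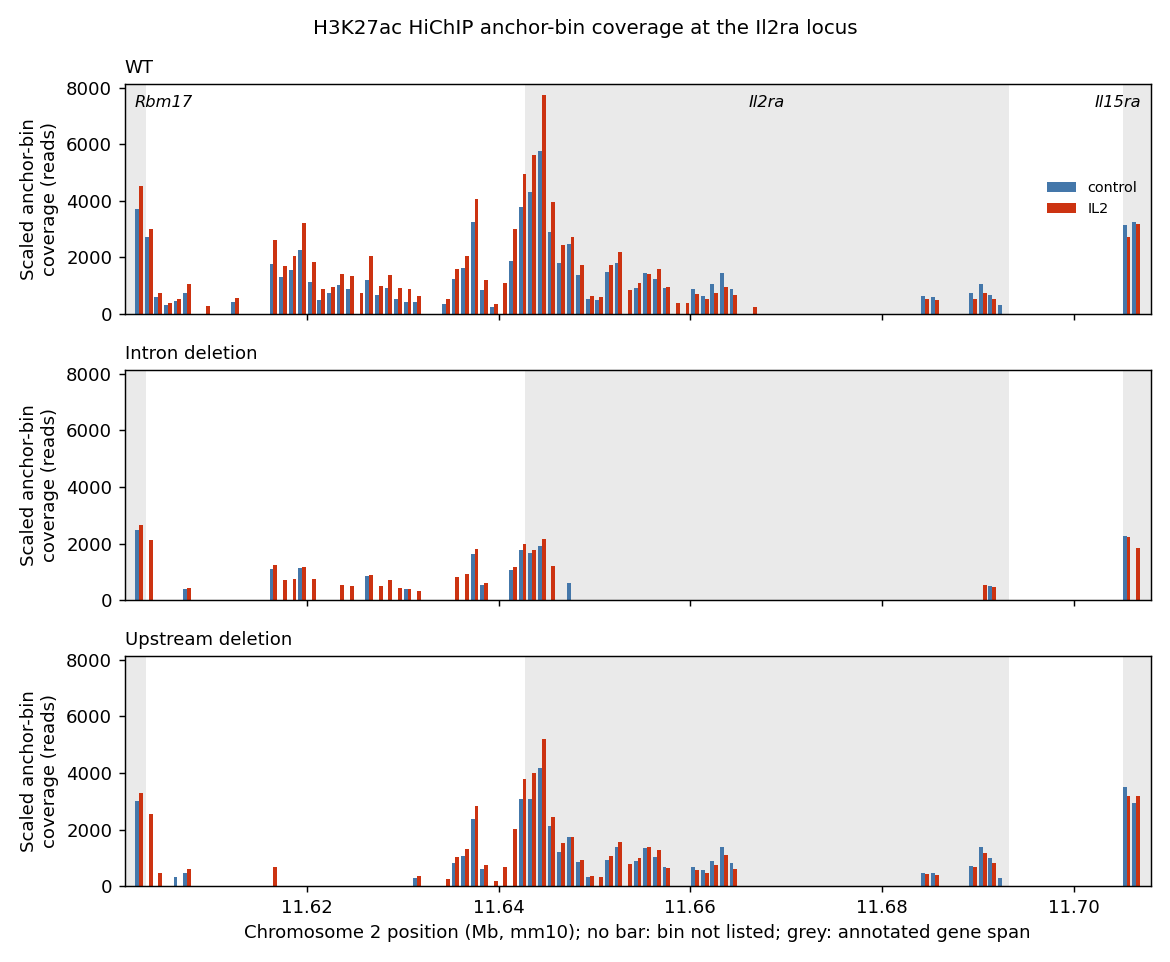
Scaled read coverage of 1 kb bins that anchored a listed loop around Il2ra on chromosome 2 (position in Mb), with 1 panel per genotype, control in blue and IL-2 in red. Grey bars mark annotated gene spans and a missing bar means that the bin was not listed; the upstream deletion listed 1 and 2 of 23 bins between 11609001 and 11632000, and the intron deletion listed 1 of 22 bins between 11645001 and 11667000 in each library.

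The promoter bin of Il2ra also had fewer listed contacts in the deletion genotypes than in WT. In part this was because its sums include contacts with these near-empty stretches. It had 32 listed pairs in the WT control library, with a mean of 34.6 and a sum of 1106 contacts (95% interval 1042 to 1173). The control library of the intron deletion had 4 pairs, with a mean of 26.3 and a sum of 105 (85.9 to 127), and that of the upstream deletion 15 pairs, with a mean of 33.0 and a sum of 495 (452 to 541). With IL-2 the sums were 1967 (1881 to 2056) over 39 pairs with a mean of 50.4 in WT, 296 (263 to 332) over 9 pairs with a mean of 32.9 in the intron deletion, and 614 (566 to 665) over 18 pairs with a mean of 34.1 in the upstream deletion. Coverage of the promoter bin, scaled for depth, was 3772 and 4953 reads in WT, 1762 and 1995 in the intron deletion, and 3092 and 3790 in the upstream deletion, for control and IL-2.

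After scaling, the summed promoter contacts of the intron deletion were 0.129 (0.105 to 0.158) of WT in control and 0.168 (0.148 to 0.190) with IL-2. With partners in its own near-empty stretch left out, an alternative chosen after seeing the data, they were 0.151 (0.119 to 0.190; 84 contacts in 3 pairs, mean 28.0, against 755 in 21 pairs, mean 36.0) and 0.230 (0.202 to 0.261; 296 in 9 pairs, mean 32.9, against 1435 in 26 pairs, mean 55.2). With unlisted pairs set to 0 or to 19 contacts the sums gave ratios from 0.129 to 0.784 and from 0.168 to 0.491. These are not limits where an anchor lay outside the authors' peaks or where a further threshold had removed pairs. Over pairs listed in both libraries the ratios were 0.554 (0.437 to 0.697; 4 pairs) and 0.455 (0.397 to 0.522; 9 pairs), and for coverage of the promoter bin 0.467 (0.439 to 0.497) and 0.403 (0.383 to 0.423). For the upstream deletion the sums were 0.513 (0.460 to 0.571) of WT in control and 0.398 (0.363 to 0.436) with IL-2, from 0.488 to 0.907 and from 0.394 to 0.669 with unlisted pairs set to 0 or to 19. Part of this gap lay in its own near-empty stretch. Without that stretch the ratios were 0.817 (0.725 to 0.921; 475 contacts in 14 pairs, mean 33.9, against 666 in 18 pairs, mean 37.0) and 0.648 (0.585 to 0.718; 565 in 16 pairs, mean 35.3, against 1111 in 22 pairs, mean 50.5). Its pairs listed in both libraries gave 0.936 (0.821 to 1.07; 12 pairs) in control, an interval that includes 1, and 0.756 (0.682 to 0.837; 17 pairs) with IL-2. Coverage of the promoter bin was 0.820 (0.781 to 0.860) and 0.765 (0.734 to 0.797) of WT. These ratios compare single libraries and have no replicate check.

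The promoter contacts were then split by region. With the 5' part of the gene body, the WT promoter had 351 contacts in control (315 to 390; 11 pairs, mean 31.9) and 532 with IL-2 (488 to 579; 13 pairs, mean 40.9). The upstream deletion had 295 (262 to 331; 10 pairs, mean 29.5) and 336 (301 to 374; 10 pairs, mean 33.6) there, and the intron deletion 21 in 1 pair in control and no listed pair with IL-2. With the 23 bins between Rbm17 and Il2ra, WT had 440 contacts in control (400 to 483; 14 pairs, mean 31.4) and 856 with IL-2 (800 to 915; 17 pairs, mean 50.4). The intron deletion had 24 in 1 pair and 133 (111 to 158; 5 pairs, mean 26.6) there, and the upstream deletion 20 in 1 pair and 49 in 2 pairs. The 4 pairs seen in any library with the bins from 11634001 to 11640000, just upstream of the promoter, held 198 and 354 contacts in WT, 40 and 141 in the intron deletion, and 142 and 147 in the upstream deletion. The 6 bins from 11602001 to 11608000, of which the first 2 hold the end of Rbm17, an RNA splicing factor gene, and the others lie up to 5 kb outside it, had 117 and 225 contacts with the Il2ra promoter in WT, in 4 and 5 pairs, against 20 and 22 in 1 pair each in the intron deletion, and 38 and 61 in 1 and 2 pairs in the upstream deletion.

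Partner bins were ranked by their mean count over the libraries that listed the pair. This leaves out libraries where a pair was below the listing limit. Counts are given for control, then IL-2. Among the first 10, the bin at 11637001, 5 kb upstream, was the one listed in all 6 libraries, with 100 and 148 contacts in WT, 40 and 61 in the intron deletion and 78 and 75 in the upstream deletion. The bin at 11647001, 5 kb downstream, held 62 and 99 contacts in WT, 49 and 70 in the upstream deletion and 21 in the control library of the intron deletion. The bin at 11619001, 23 kb upstream, held 58 and 90 in WT and 24 and 30 in the intron deletion, and was not listed in the upstream deletion. The bins at 11626001, 11628001 and 11618001 held 40 and 79, 35 and 76, and 36 and 54 contacts in WT. The intron deletion listed the first and the second of them with IL-2, at 23 and 24 contacts, and the upstream deletion listed none of the 3. The bins at 11635001 and 11636001 held 45 and 83, and 53 and 81, contacts in WT. They held 47 and 33 with IL-2 in the intron deletion, and between 29 and 36 in the upstream deletion. The bins at 11652001 and 11648001, inside the gene, held 51 and 61, and 42 and 74, in WT and between 32 and 44 in the upstream deletion, and were not listed in the intron deletion.

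**Figure D2:**
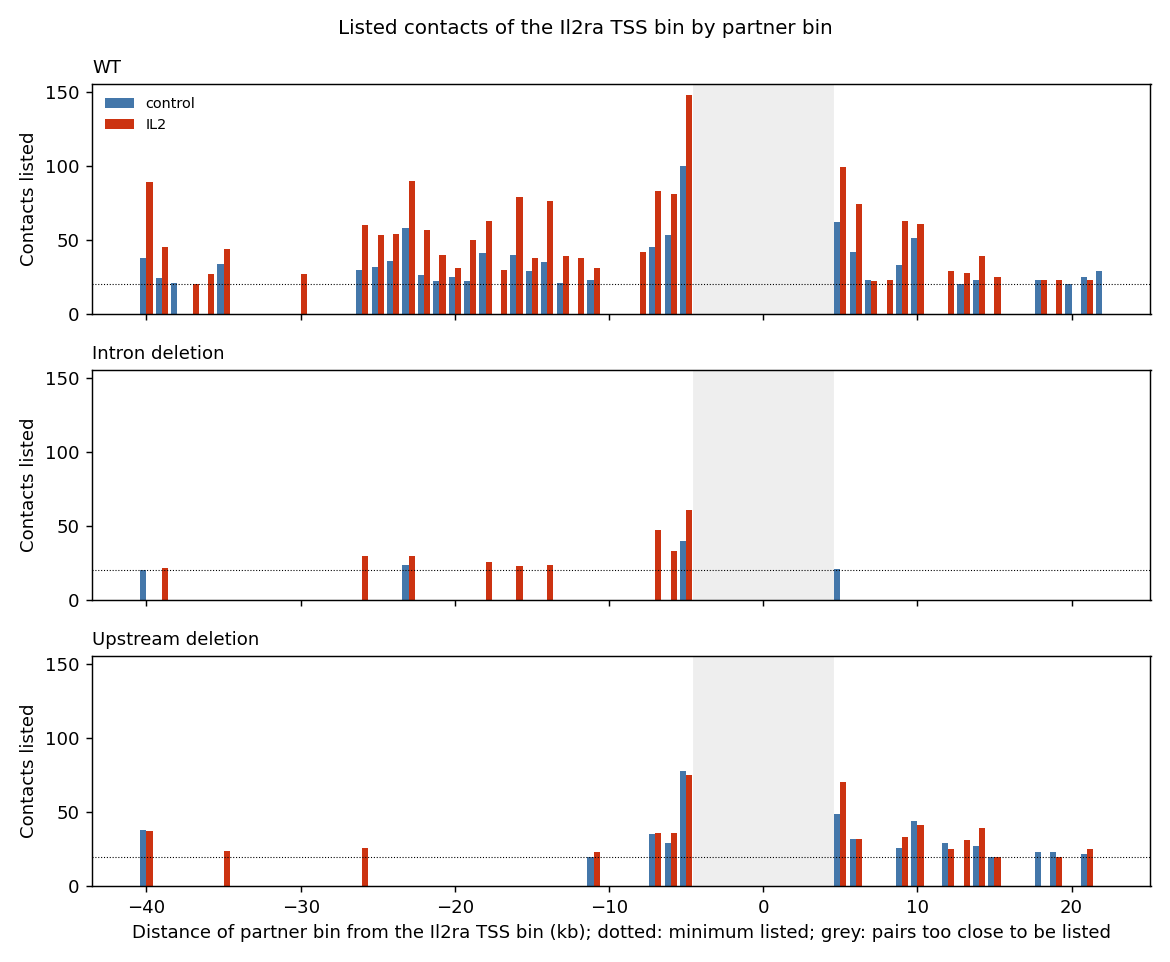
Listed contacts (read pairs, not scaled) of the Il2ra promoter bin with partner bins by distance in kb, with 1 panel per genotype, control in blue and IL-2 in red; the dotted line marks the listing minimum of 20 and grey marks partners too close to be listed. WT had 32 and 39 listed pairs, the intron deletion 4 and 9 and the upstream deletion 15 and 18; a pair farther downstream is not drawn.

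With IL-2, the summed promoter contacts of Il2ra were 1.53 times the control value in WT (1.43 to 1.65), and from 1.31 to 1.58 with unlisted pairs set to 0 or to 19. In the upstream deletion the ratio was 1.19 (1.06 to 1.34), with 1.03 to 1.23 in the same way, and in the intron deletion 1.99 (1.59 to 2.52), with 0.880 to 2.25. Over pairs listed in both libraries the ratio was 1.40 in WT (1.30 to 1.52; 29 pairs), 1.04 in the upstream deletion (0.917 to 1.18; 14 pairs) and 1.01 in the intron deletion (0.723 to 1.41; 2 pairs), and the last 2 intervals include 1. Coverage of the promoter bin was 1.31 (1.26 to 1.37), 1.23 (1.17 to 1.29) and 1.13 (1.06 to 1.21) times the control value in WT, the upstream deletion and the intron deletion. Of the 43 promoter pairs listed in any library, 1 was listed in all 6, the pair with the bin 5 kb upstream, and over that pair the ratio for the upstream deletion was below 1 (78 contacts in control, 75 with IL-2).

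The next comparison asked what IL-2 changed genome-wide. Promoter contacts, counted at gene ends, both rose and fell with IL-2, with 3 libraries per treatment. Cish and Socs1, feedback inhibitors of cytokine signalling, rose by log2 0.44 (SE 0.06, adjusted p = 2.61e-04; fold 1.36) and 0.31 (SE 0.06, adjusted p = 0.00557; fold 1.24). The 10 largest rises ran from log2 0.58 to 0.86 and included Fosl1, a subunit of the transcription factor AP-1 (0.68), Kdm3a, a histone H3K9 demethylase (0.66), Arid5a, an RNA-binding protein that stabilises cytokine transcripts (0.61), and Rmi2, a partner of the Bloom helicase (0.61). The 10 largest falls ran from −0.81 to −0.51 and included Sesn3, a stress-induced inhibitor of mTORC1 (−0.81), Trp53inp1, a p53-induced stress gene (−0.72), Btg2, an antiproliferative gene (−0.58), Rbl2, a member of the retinoblastoma family (−0.57), and Ccng2, an atypical cyclin that restrains the cell cycle (−0.51).

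The other large rises were at Ccdc116 (0.86), Becn1, an autophagy gene (0.79), Gps2, a subunit of a corepressor complex (0.70), Slc5a6, a vitamin transporter, which shares its bins with Atraid (0.63), Psme3, a proteasome activator (0.60), and Plcb3, a phospholipase C gene, which shares its bins with Ppp1r14b (0.58). The other large falls were at Ctsd, a lysosomal protease (−0.73), Igfbp6, an insulin-like growth factor binding protein (−0.65), Dnajc15 (−0.56), Nup50, a nuclear pore gene (−0.54), and Spns1, a lysosomal transporter (−0.54). Adjusted p-values of these 20 genes lay between 0.00115 (Rmi2) and 0.0462 (Nup50), and the SE between 0.09 and 0.20. Values at Ccdc116, Becn1, Gps2, Fosl1, Atraid/Slc5a6, Sesn3, Ctsd and Igfbp6 rest on 1 shared loop each, some with counts near the minimum of 20. Genes of the same locus were among them, since Becn1 (11:101288258–101302286) and Psme3 (11:101316213–101323537) lie close together, as do Rmi2 (16:10835059–10843235) and Socs1 (16:10783808–10785536). The sign of Atraid/Slc5a6 turned to −0.04 when the coverage of its bins was used in place of contacts. Il2ra itself did not pass the test (log2 0.12, SE 0.14, adjusted p = 0.703). That value rests on 1 shared loop, with the bin 5 kb upstream, and leaves out all other promoter pairs.

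Of 16 measured direct targets of IL-2 and STAT5, the transcription factor that IL-2 activates, 6 rose (Cish, Socs1, Osm 0.34, Tnfrsf18 0.31, Il2rb 0.29 and Pim2 0.26), 1 fell (Mcl1, a survival gene, −0.38) and 9 did not pass. Adjusted over the list alone, 7 rose and 1 fell. As a set they rose against other genes in camera (adjusted p = 4.22e-06, median log2 0.21), with p = 0.0594 and adjusted p = 0.535 with an estimated correlation. By fry, which tests whether the set moves one way on its own, adjusted p = 0.135. Of 5 measured genes of growth and ribosome biogenesis none passed, though the glucose and amino acid transporter genes Slc2a1 (0.38, adjusted p = 0.0821) and Slc7a5 (0.55, adjusted p = 0.157) were the 2 that rose when adjusted over the list alone (camera adjusted p = 0.0798). Of 11 genes of cytokine receptors and their kinases and STAT proteins, mostly of the common gamma chain family, Il2rb, the beta chain of the IL-2 receptor, rose and 10 did not pass (3 rose adjusted over the list alone; camera adjusted p = 0.415). Of the 3 measured Il2ra locus genes, Prkcq, a kinase of T cell receptor signalling, rose by 0.44 (SE 0.06, adjusted p = 2.61e-04; 1 rose adjusted over the list alone), and Il2ra and Il15ra did not pass (camera adjusted p = 0.0798). Without the WT control or the WT IL-2 library Prkcq kept its rise (0.38 in each case) and no longer passed (adjusted p = 0.057 and 0.0593), and Cish (0.43 in each case) still passed (adjusted p = 0.0305 and 0.0304).

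Of 14 measured genes of T cell identity, Cd3d and Cd3g, subunits of the T cell receptor complex, fell by 0.31 and 0.37 and 12 did not pass (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.209). Of 8 naive and memory genes none passed. Il7r, the IL-7 receptor, had 0.48 (adjusted p = 0.0726) and S1pr1, which directs exit from lymphoid organs, −0.35 (adjusted p = 0.0539), and these were the 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.823). Of 9 activation and checkpoint genes, Egr1, an early response transcription factor, rose (0.34; 1 rose adjusted over the list alone; camera adjusted p = 0.895), and Ctla4 did not pass (−0.22, adjusted p = 0.207). Of 5 cytotoxic effector genes none passed in either count, with Tnf at 0.13 and Nkg7 at −0.18 (camera adjusted p = 0.501). Of 7 housekeeping genes, Rpl13a and Actb rose (0.38 and 0.29; 2 rose adjusted over the list alone; camera adjusted p = 0.0798), with the same sign under each scaling. Markers of other cell types were rarely measured. Ikzf2, of regulatory T cells, Cd79a, of B cells, and Cd68 and Tyrobp, of myeloid cells, did not pass in any comparison, and no NK cell or erythroid marker was measured.

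**Figure D3:**
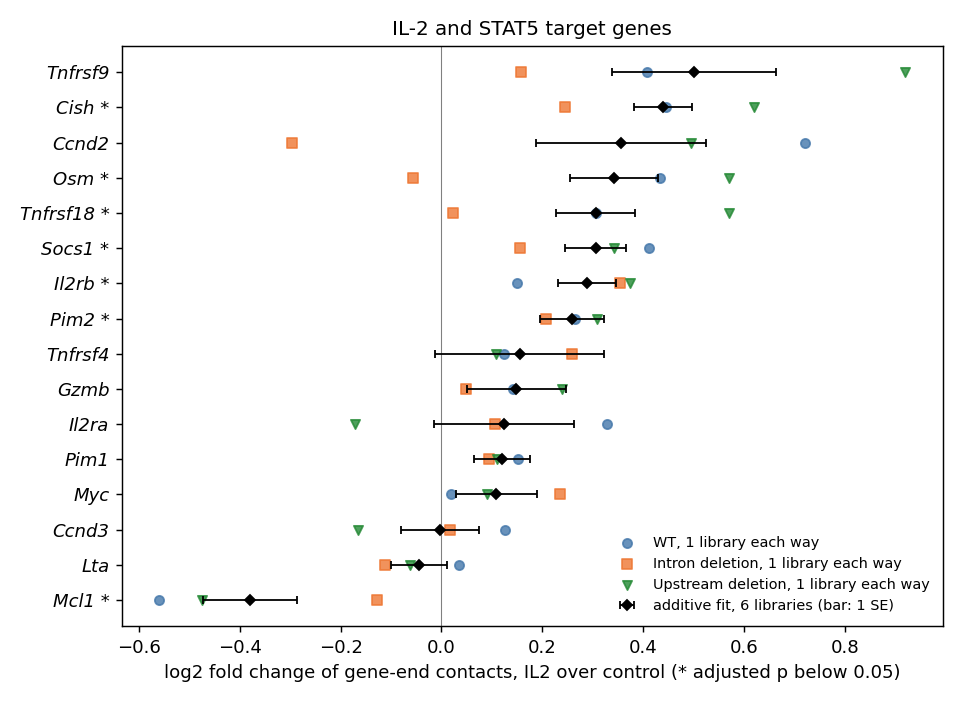
Log2 fold change of gene-end contacts with IL-2 against control for each measured IL-2 and STAT5 target gene. Black diamonds with bars give the fit over all 6 libraries with 1 SE. Filled symbols give the change within WT (blue circles), the intron deletion (orange squares) and the upstream deletion (green triangles). Asterisks mark adjusted p below 0.05, with 6 genes that rose and 1 that fell.

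In all, 99 of 2489 gene ends passed with IL-2, 53 up and 46 down, and 924 of 28033 shared loops, 719 up and 205 down. Of these, 94 gene ends and 821 loops moved the same way in each genotype. The loops with the largest rises lay beside the neighbours of Cish, from the bin at 9:107336001 inside Hemk1 to 9:107341001 inside 6430571L13Rik (log2 1.47, adjusted p = 1.50e-12) and from 9:107309001 to 9:107336001 (1.17, adjusted p = 9.29e-11). Others joined the bin at 17:35204001 inside Lta, which encodes lymphotoxin alpha, to 17:35231001 inside Nfkbil1 (1.33, adjusted p = 1.19e-10) and to 17:35211001 (1.16, adjusted p = 1.94e-10), and joined 5:3461001 to 5:3466001 inside Cdk6, a cell cycle kinase (1.19, adjusted p = 1.44e-06). The largest falls were from 7:127182001 to 7:127189001 (−1.05), from 10:127142001 to 10:127167001 inside B4galnt1 (−0.93), from 7:127188001 to 7:127194001 inside Cd2bp2 (−0.91), from 4:11146001 to the end of Trp53inp1 at 4:11156001 (−0.90) and from 8:126859001 to 8:126866001 (−0.90), with adjusted p from 2.98e-05 to 0.00230.

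The numbers of calls with IL-2 depended on the libraries and the tool. Leaving out either library of a genotype leaves the IL-2 contrast to the other genotypes alone, so such pairs of counts are not separate checks. Without the WT control or the WT IL-2 library, 47 and 46 loops and 5 and 5 gene ends passed (Arid5a, Cish, Kdm3a, Rmi2 and Trp53inp1 in both cases); without the upstream deletion control or IL-2 library, 62 and 68 loops and 21 and 20 gene ends. Without the intron deletion control or IL-2 library the counts were 1823 and 1825 loops and 408 and 325 gene ends, and without both 1807 loops (1214 up, 593 down) and 325 gene ends (151 up, 174 down). DESeq2's Wald test called 10 gene ends and 0 loops, with 639 loops at an unadjusted p under 0.05 against 4129 in edgeR. Scaling by distance class gave 113 gene ends, 73 up and 40 down. Of the 29 named genes past the threshold, 5 remained past it without the WT control or the WT IL-2 library, 28 and 26 without the intron deletion control or IL-2 library, and 12 and 11 without the upstream deletion control or IL-2 library.

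Across the 18580 shared bins, which are not independent replicates, the change in coverage with IL-2 in WT correlated with that in the upstream deletion at r = 0.904 (rho 0.866) and with that in the intron deletion at r = 0.506 (rho 0.490). The SD of the change across bins was 0.26 in WT, 0.30 in the upstream deletion and 0.11 in the intron deletion on the log2 scale. The slope on the WT change was 1.02 for the upstream deletion and 0.216 for the intron deletion. Across loops the same correlations were 0.415 and 0.104. A test of the intron deletion's response against that of the other genotypes, chosen after seeing the data, passed for 58 gene ends, 10 loops and 3990 bins. Its 1 residual degree of freedom comes from the gap between the WT and upstream deletion responses. The intron deletion's response rests on 1 pair of libraries with no spread of its own.

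**Figure D4:**
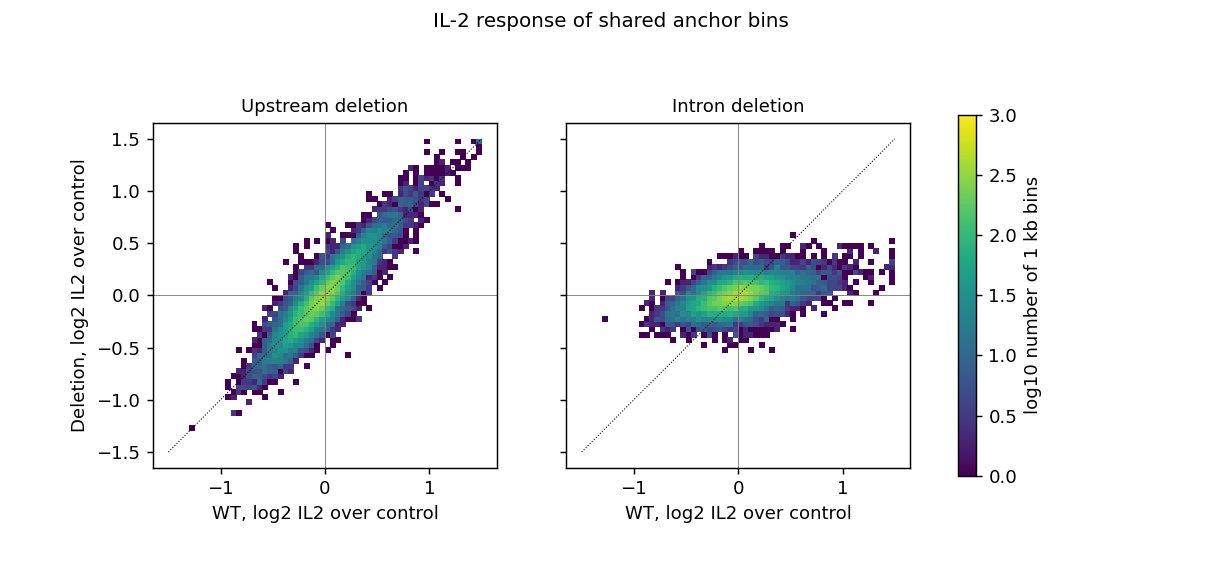
Log2 change in bin coverage with IL-2 in WT (x axis) against the upstream deletion and the intron deletion (y axes, 1 panel each) over 18580 shared bins; colour gives the log10 number of bins and the dotted line marks equal change. The SD of the change was 0.30 in the upstream deletion and 0.11 in the intron deletion, against 0.26 in WT, and values beyond 1.5 are drawn at the limit.

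The intron deletion was then compared with WT over both treatments, to find contacts that differ away from Il2ra as well as at it. Contacts fell most at Apobec3, an antiviral cytidine deaminase gene (15:79892058–79918218), by log2 −2.91 (SE 0.17, adjusted p = 1.48e-10; fold 0.133), with 254 and 292 contacts in WT against 23 and 34 in the intron deletion, and 194 and 169 in the upstream deletion. The largest rise was at Fam240a (9:110914376–110916898), by 2.11 (SE 0.14, adjusted p = 8.02e-10; fold 4.31). Bin coverage moved the same way. For control and IL-2 it differed from WT by −1.94 and −2.01 at 15:79892001 and by −4.32 and −4.05 at 15:79900001, both at Apobec3. At 9:110916001 in Fam240a it differed by 1.73 and 2.00. Contacts were not scaled by the coverage of their own anchors, so a change in contacts may be a change in the mark there. Il2ra fell by −0.96 (SE 0.17, adjusted p = 7.79e-04), and on the same chromosome Prkcq (2:11171905–11301226) rose by 0.86 (SE 0.07, adjusted p = 3.49e-08; 979 and 1700 contacts in WT, 1390 and 2437 in the intron deletion). The fall at Il2ra rests on 1 shared loop, 5 kb upstream of the promoter. It did not pass without the WT IL-2 library (−0.74, adjusted p = 0.0991) or the intron deletion IL-2 library (−0.95, adjusted p = 0.0513), with DESeq2's Wald test (adjusted p = 0.0724), or with unlisted pairs as 0 (−2.003, adjusted p = 0.0696).

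Further rises were at Rarg, a retinoic acid receptor (1.39), Ccdc69 (1.38), Kbtbd11 (1.33), Kif11, a mitotic kinesin (1.32), Gm33887 (1.30), Nup214, a nuclear pore gene (1.21), Tent5c, a poly(A) polymerase (1.13), Cracr2a, a calcium sensor (1.09), and Bbof1 (1.08). Further falls were at Tnfaip8 (−1.21), Dusp4, a phosphatase of MAP kinases (−1.11), Il12rb2, a chain of the IL-12 receptor (−1.11), Batf3, a transcription factor of the AP-1 family (−1.05), Pkp3 (−1.04), Satb1, a chromatin organiser of T cells (−1.02), Fosl1 (−1.002) and Ajuba/Haus4, which share their bins (−0.95). Adjusted p-values of these 20 largest changes, Apobec3, Fam240a and Il2ra included, were between 1.48e-10 and 0.00744. Il2ra, Rarg, Kif11, Gm33887, Nup214, Tent5c, Bbof1, Apobec3, Tnfaip8, Il12rb2, Batf3, Pkp3, Fosl1 and Ajuba/Haus4 rest on 1 shared loop each. Some counts lay near the minimum of 20, as at Rarg (20 and 20 in WT, 34 and 49 in the intron deletion). The 24 named genes past the threshold kept their sign under every alternative. Il15ra, with 20 to 29 contacts per library, did not pass (0.39, adjusted p = 0.478). It turned to −0.24 by bin coverage (adjusted p = 0.0235) and to −0.9993 with unlisted pairs as 0 (adjusted p = 0.380).

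Of the 16 IL-2 and STAT5 targets, 2 rose in the intron deletion (Mcl1 0.49 and Ccnd3, a D-type cyclin, 0.32), 7 fell and 7 did not pass (3 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.0658). The 7 falls were at Il2ra, Osm (−0.49), Gzmb, a granzyme of killer cells (−0.37), Il2rb (−0.30), Pim1, a survival kinase (−0.29), Cish (−0.27) and Lta (−0.25). These values pool both treatments, and the change with IL-2 was smaller in the intron deletion across bins. Control and IL-2 values were −0.17 and −0.37 at Cish, −0.40 and −0.20 at Il2rb, and −0.84 and −1.06 at Il2ra. Over 16 alternatives the call held in 8 at Cish, 11 at Il2rb and 12 at Il2ra. Of 5 cytotoxic effector genes, Gzmb and Nkg7, a granule protein (−0.35), fell and 3 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0658). Of 11 cytokine receptor and signalling genes, 3 rose, among them the kinase gene Jak1 (0.43) and the common gamma chain gene Il2rg (0.31), Il12rb2 and Il2rb fell and 6 did not pass, the same numbers adjusted over the list alone (camera adjusted p = 0.979). The median and mean of that list were negative while fry gave it an upward direction. Of 8 naive and memory genes, Ccr7, a homing receptor of naive cells, rose (0.53), Satb1 fell and 6 did not pass (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.337). Of 14 T cell identity genes, Cd8b1 rose (0.35) and 13 did not pass (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.337). Of 9 activation genes, Irf4, a transcription factor of activated lymphocytes, fell (−0.68; 1 fell adjusted over the list alone), with a median of 0.03, a mean of −0.02 and a downward direction in camera (adjusted p = 0.800). Of 7 housekeeping genes 1 fell and 6 did not pass (1 fell adjusted over the list alone), none of the 5 growth genes passed, and of the 3 Il2ra locus genes Prkcq rose and Il2ra fell (camera adjusted p = 0.361 for each of these lists).

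In all, 335 of 2489 gene ends (188 up, 147 down) and 3166 of 28033 loops (1757 up, 1409 down) differed between the intron deletion and WT. Of these, 335 and 3138 differed the same way with and without IL-2. The largest falls among loops were inside Apobec3, from 15:79892001 to 15:79900001 (−2.97, adjusted p = 4.99e-54), and between 15:74933001 and the end of Ly6e, a lymphocyte surface protein gene, at 15:74955001 (−2.03, adjusted p = 3.94e-17), with neighbouring pairs from 15:74935001 and 15:74934001 to 15:74954001 (−1.85 and −1.73). Another joined 17:29079001 to 17:29094001 inside Cdkn1a, a cell cycle inhibitor gene (−1.73, adjusted p = 3.65e-13). The loop inside Apobec3 is also the 1 shared loop behind its gene-end value. The largest rises joined 9:110908001 to the bins at 9:110915001, 9:110916001 and 9:110917001 at Fam240a (2.40, 2.21 and 2.18), 13:73703001 to 13:73709001 (2.14), and 9:110897001 inside Als2cl to 9:110906001 (2.07), with adjusted p from 1.80e-36 to 7.44e-15.

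Without the WT control, WT IL-2 or intron deletion IL-2 library, 1113, 494 and 793 loops and 127, 79 and 115 gene ends passed. Of the 24 named genes past the threshold, 21, 14 and 14 remained past it, and each of the 10 named loops did. DESeq2's Wald test called 119 loops and 57 gene ends, and with unlisted pairs as 0 the edgeR fit called 0 of 66781 loops (6715 at an unadjusted p under 0.05) and 3 gene ends (Apobec3, Ly6e and Lad1). Scaling by bin coverage moved the median log2 change over all loops from −0.01 to 0.10, with 2692 loops up and 810 down and 229 gene ends up and 83 down. Scaling by distance class gave 141 gene ends up and 209 down.

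The upstream deletion was compared with WT in the same way, and few contacts passed. Irgm2, an interferon-induced GTPase gene (11:58214977–58222783), rose by log2 0.74 (SE 0.08, adjusted p = 3.16e-05; fold 1.67), with 1189 and 1176 contacts in WT and 1605 and 1499 in the upstream deletion. It held 1329 and 2092 in the intron deletion, log2 0.65 and 1.05 above WT after scaling. H2bu2, a histone H2B gene, rose by 0.75 (SE 0.10, adjusted p = 6.45e-04), Gimap8, a GTPase of lymphocytes, by 0.40 (SE 0.07, adjusted p = 0.00589) and Prkcq by 0.32 (SE 0.07, adjusted p = 0.0424). Il2ra did not pass (−0.34, SE 0.16, adjusted p = 0.437), nor did Il15ra (0.72, SE 0.23, adjusted p = 0.322). Each of these values rests on 1 shared loop, and that of Il2ra leaves out all its other promoter pairs. Prkcq kept its rise and no longer passed without the WT control (0.24, adjusted p = 0.736), WT IL-2 (0.41, adjusted p = 0.511), upstream deletion control (0.33, adjusted p = 0.193) or upstream deletion IL-2 library (0.31, adjusted p = 0.205).

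The other named rises were at Gm33887 (1.13), Degs1, an enzyme of ceramide synthesis (0.73), Pdzd8, a lipid transfer protein (0.56), 1700056E22Rik (0.41), Ms4a6c (0.35) and Fyco1, an adaptor of vesicle transport (0.34). The falls were at Trmt10c, a mitochondrial tRNA methyltransferase (−0.54), Med22 and Rpl7a, which share their bins (−0.53), Cdca5, a regulator of sister chromatid cohesion (−0.35), and Vps52, a subunit of a vesicle tethering complex (−0.30). Each of the largest rises was also above WT in both intron deletion libraries. The falls were also below WT there, except Trmt10c with IL-2 (0.01). Both comparisons use the same WT libraries, so these changes need not be particular to the upstream deletion. In all, 18 of 2489 gene ends (14 up, 4 down) and 22 of 28033 loops (13 up, 9 down) passed, each moving the same way in both treatments. The largest rises among loops joined the ends of H2bu2 and H2aw/Trim17, from 11:58949001 to 11:58954001 (1.85, adjusted p = 4.30e-25), and the ends of Igtp and Irgm2, from 11:58199001 to 11:58214001 (1.35, adjusted p = 5.98e-17). Others joined the end of Pdzd8 at 19:59345001 to 19:59350001 (1.23), and X:167101001 to X:167205001 (1.11). The largest falls were inside Srebf1, a regulator of lipid synthesis, from 11:60210001 to 11:60220001 (−1.28, adjusted p = 2.21e-06), from the end of Rps18/Vps52 at 17:33955001 to 17:34001001 (−1.12), from Ifnar2 to the end of Il10rb at 16:91373001 and 16:91406001 (−1.10), from 7:126355001 to 7:126368001 inside Lat, a T cell receptor adaptor gene (−1.08), and inside Syne3 from 12:105000001 to 12:105008001 (−1.06).

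Of the 11 cytokine receptor and signalling genes none passed in the upstream deletion. Adjusted over the list alone 5 rose, among them Il4ra (0.26), Jak1 (0.25), Stat5a/Stat5b (0.22) and Il15ra, and the set rose in camera (adjusted p = 0.00608), with p = 0.0703 and adjusted p = 0.633 with an estimated correlation, and adjusted p = 0.0358 in fry. No list call in any comparison held with an estimated correlation. None of the 16 IL-2 and STAT5 targets (camera adjusted p = 0.647), 5 growth genes (0.539), 9 activation genes (0.844), 14 T cell identity genes (0.362), 8 naive and memory genes (0.149), 7 housekeeping genes (0.840) or 5 cytotoxic genes (0.840) passed over all genes. Adjusted over the list alone, 2 naive and memory genes, among them Ccr7, and 1 T cell identity gene (Runx1) rose and 1 housekeeping gene (Eef1a1) fell. Cytotoxic genes had a median of −0.04 and a mean of 0.05, and housekeeping genes a median of 0.08 and a mean of −0.07. Of the 3 locus genes Prkcq rose and 2 did not pass, while 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.219).

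These counts were small and moved with single libraries. Without the WT control or WT IL-2 library 4 and 3 loops and 4 and 1 gene ends passed, and without the upstream deletion control or IL-2 library 5 and 4 loops and 2 and 21 gene ends. Without the intron deletion control or IL-2 library 85 and 86 loops and 126 and 68 gene ends passed. Irgm2 was the 1 gene end called without the WT IL-2 library and the 1 called by DESeq2's Wald test, which called 2 loops (11:58949001–58954001 and 11:58199001–58214001) and had 117 loops at an unadjusted p under 0.05 against 2294 in edgeR. Scaling by bin coverage gave 40 loops up and 9 down, and scaling by distance class gave 3 gene ends up and 6 down, without Prkcq (adjusted p = 0.143).

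Both deletion genotypes were compared with the same WT libraries, so their differences share the chance values of these libraries. Across loops, which are not independent replicates, the changes correlated at r = 0.480, against 0.454 in a simulation with no effect, with a covariance of 0.0513 against 0.0251. Of the 22 loops called in the upstream deletion, 21 had the same sign in the intron deletion. Called in both were 9 loops up and 4 down, against 0.815 and 0.452 for independent lists. That comparison leaves out the shared WT libraries. In 100 simulated draws with no effect that kept them, lists of the same sizes had 21.1 of 22 loops with the same sign, and 9.52 up and 2.96 down in both, on average. The overlap and the shared signs thus do not separate a shared effect from the shared WT libraries. The covariance exceeded its simulated value, and the cause of that excess was not tested.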

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

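In this part, all tests except the depth test and the first mixed-sample test were chosen after the result was seen. The IL-2 response of the intron deletion differed from that of the other genotypes by a test of the difference itself, in edgeR, which passed for 58 of 2489 gene ends (40 with a higher and 18 with a lower value in the intron deletion), 10 of 28033 loops and 3990 of 18580 bins. No other tool was run. This test has 1 residual degree of freedom, which comes from the gap between the WT and upstream deletion responses, and the intron deletion's response rests on 1 pair of libraries with no spread of its own. Of the 58 gene ends, 48 changed less in the intron deletion than in both other genotypes. These gene ends were picked by that difference, and the intron deletion's change varied less across bins. That raises the share in advance, so it is no further support.

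Among the genes the report names, 15 passed, of which 7 were named by the rule for the IL-2 comparison. Cish, a feedback inhibitor of cytokine signalling, rose less in the intron deletion by −0.28 on the log2 scale (adjusted p = 0.0136), with 0.45 in WT, 0.25 in the intron deletion and 0.62 in the upstream deletion. Rmi2, of DNA repair, differed by −0.56 (adjusted p = 0.00111; 0.89, 0.26 and 0.73) and Tnf, an inflammatory cytokine gene, by −0.32 (adjusted p = 0.0394; 0.28, −0.08 and 0.18). The other 4 of these 7 genes fell less in the intron deletion. Trp53inp1, a stress gene, differed by 0.63 (adjusted p = 0.0381; −0.94, −0.29 and −0.89), Dnajc15 by 0.63 (adjusted p = 0.00119; −0.84, −0.15 and −0.72), Ccng2, a cyclin that restrains division, by 0.66 (adjusted p = 0.0015; −0.64, −0.07 and −0.84) and Cd3d, of the T cell receptor complex, by 0.41 (adjusted p = 0.00288; −0.41, −0.04 and −0.48). The report names the other 8 for other reasons. Lower values in the intron deletion were at Osm (−0.55, adjusted p = 0.00265; 0.43, −0.06 and 0.57) and Tnfrsf18 (−0.40, adjusted p = 0.0184; 0.31, 0.02 and 0.57), and at Hemk1 (−0.64, adjusted p = 2.64e-09; 0.67, 0.06 and 0.74) and 6430571L13Rik (−0.64, adjusted p = 8.51e-09; 0.67, 0.06 and 0.74), both beside Cish. Higher values were at Irgm2 (0.38, adjusted p = 0.0004; −0.25, 0.15 and −0.21), B4galnt1 (0.31, adjusted p = 0.00404; −0.24, 0.08 and −0.22), Fyco1 (0.30, adjusted p = 0.0252; −0.37, −0.10 and −0.42) and Fam240a (0.59, adjusted p = 0.0325; −0.44, 0.10 and −0.54).

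The IL-2 response across bins was thus smaller in the intron deletion, with a slope of 0.216 on the WT response against 1.02 for the upstream deletion. Against a difference in depth, every library was thinned to the same total coverage. The SD of the WT response stayed 2.31 times that of the intron deletion. For swapped libraries or an untreated IL-2 library, the lowest slope on the WT response over fits leaving out 1 chromosome was 0.213, above 0. The measured change thus ran the same way as in WT. Those fits reuse the same libraries and measure no spread between libraries, so they cannot decide on a swap or an untreated library. A mixed sample, with part of the IL-2 library from untreated cells, should keep the same share of every change, and bins that rose kept 18.5% and bins that fell 27.6%, a difference of −9.30 jackknife SE; but that SE left out the error of scaling, other scalings chosen afterwards gave −8.89, −15.9 and 6.45, and a shift of the intron deletion by log2 0.0195 made the shares equal, so the bound of 2 SE set beforehand was too narrow and this stays open. Less IL-2 receptor in cells with the intron deletion is a biological hypothesis that also stays open: the intron deletion minus WT difference with IL-2 ran against the upstream deletion's response (r = −0.441 across bins, which are not independent replicates), a value that the smaller response nearly implies. A mixed sample and less receptor cannot be told apart with 1 library per genotype and treatment. A difference in library quality was not tested as a cause. The deposited expected count exceeded the contact count for 31.9% and 33.5% of listed loops in the control and IL-2 libraries of the intron deletion. In the other libraries this share lay between 8.92% and 19.1%.

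The other splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 924 loops and 99 gene ends with IL-2, and the highest other split 8 and 0 (edgeR). Thus 1 of the 10 splits, the real one, gave a result as large in each case. But the genotype term was kept, so the IL-2 effect entered the residual spread of every other split. That lowers their calls in advance, and in some of them the contrast rested on 1 pair of libraries. These counts decide nothing about chance.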

How the results depend on the processing

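In this part, scaling by bin coverage, leaving out both intron deletion libraries, the gene span, the coverage of bins and the pairs outside a deletion genotype's near-empty stretch were chosen after the data were seen. Ratios of Il2ra promoter contacts kept their direction under the alternatives below, except where named as reversed or on both sides of 1. Their size moved. With unlisted pairs set to 0 or to 19 contacts, the ratio of IL-2 to control in the intron deletion ran from 0.880 to 2.25, on both sides of 1, and the other ratios kept their side. Scaled by the contact sum of all listed loops, IL-2 against control was 1.29 in WT and 1.37 in the intron deletion, the intron deletion against WT 0.189 in control and 0.1997 with IL-2, and the upstream deletion 0.597 and 0.510. With the bins on either side of the promoter bin, IL-2 against control was 1.67 in WT, 2.85 in the intron deletion and 1.58 in the upstream deletion, and in control libraries the ratio to WT was 0.0957 for the intron deletion and 0.408 for the upstream deletion. Over the loop listed in all 6 libraries, IL-2 against control was 1.28 in WT, 1.08 in the intron deletion and, reversed, 0.923 in the upstream deletion, and the ratios to WT were 0.544 and 0.460 for the intron deletion and 0.894 and 0.646 for the upstream deletion. By coverage of the promoter bin, IL-2 against control was 1.31 in WT and 1.13 in the intron deletion, and the ratios to WT were 0.467 and 0.403, and 0.820 and 0.765. Over pairs outside the near-empty stretch of the deletion genotype, the ratio to WT with IL-2 was 0.230 for the intron deletion, and the ratios of the upstream deletion were 0.817 and 0.648. The cause was not tested.

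At a minimum of 40 contacts, 19050 and 27453 loops were listed in WT, 8685 and 20322 in the intron deletion and 13735 and 15859 in the upstream deletion, for control and IL-2. Matching within 1 bin raised the overlap of control and IL-2 loops to 0.820 in WT, 0.733 in the intron deletion and 0.810 in the upstream deletion, and the overlap with WT to 0.675 and 0.757 for the intron deletion and 0.827 and 0.799 for the upstream deletion. Over equal numbers of top loops the overlaps were 0.618 in WT and 0.646 in the intron deletion, and with WT 0.544 and 0.536, and 0.631 and 0.651. A looser match raises an overlap by construction.

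Counts of calls follow in the order IL-2, intron deletion and upstream deletion, by edgeR unless DESeq2 is named. DESeq2's Wald test called 0, 119 and 2 loops (639 at an unadjusted p under 0.05 for IL-2) and 10, 57 and 1 gene ends. With unlisted pairs as 0, 0, 0 and 0 loops (2582, 6715 and 1867 unadjusted) and 0, 3 and 0 gene ends (315 and 157 unadjusted where 0) passed. A mean of at least 50 contacts left 1724 loops for the intron deletion, with fewer loops tested. The upper part by count left 34 and 5 gene ends for IL-2 and the upstream deletion. Without the genotype term 0 loops and 0 gene ends passed for IL-2 (2058 and 204 unadjusted), and without the treatment term 1052 and 2 loops and 102 and 0 gene ends (136 unadjusted) for the deletions. Without both intron deletion libraries IL-2 changed 1807 loops and 325 gene ends. Scaling by bin coverage called 49 loops, and scaling by distance class 9 gene ends, for the upstream deletion. Over the gene span 506 and 7 genes passed for the deletions, and by coverage of gene-end bins 0 (1144 unadjusted), 1095 and 1. Leaving out 1 library at a time gave 46 to 1825, 494 to 3285 and 3 to 86 loops and 5 to 408, 79 to 495 and 1 to 126 gene ends. The cause of these moves was not tested.

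With IL-2, 1 gene list passed in camera. With an estimated correlation 0 lists passed (0 unadjusted) and with fry 0 (1 unadjusted); without both intron deletion libraries 3 passed, over the gene span 2, and leaving out 1 library 1 to 3. The targets of STAT5 rose and passed without each library. Both leave-outs of a genotype rest on the same other genotypes, so they are not separate checks. Housekeeping and Il2ra locus genes also passed without either intron deletion library, and growth and Il2ra locus genes without either upstream deletion library. Lists were not run with libraries left out for the deletion comparisons.

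Of the values for single named genes, loops and gene lists under other settings, 1588 kept their direction and side of the threshold, 509 kept their direction and lost the call, 36 gained it and 60 reversed. In 2 of the 60 the reported or the other value had passed: Atraid/Slc5a6 with IL-2 (−0.0447, adjusted p = 0.431) and Il15ra in the intron deletion (−0.242, adjusted p = 0.0235), both by coverage of gene-end bins. In the other 58 neither passed, with adjusted p of 0.0605 or more under the other setting, and their cause was not tested.

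Those 58 follow, as log2 changes for genes. By coverage of gene-end bins, the intron deletion had −0.262 at Socs1, −0.0365 at Cd3g, 0.162 at Egr1 and 0.0597 at Slc2a1, and the upstream deletion −0.0271 at Socs1. By the same measure 3 gene lists turned with IL-2, activation, cytokine receptor and naive and memory genes (adjusted p = 0.834 for each). With unlisted pairs as 0, Nkg7 had 0.0166 with IL-2. The intron deletion then had −0.9993 at Il15ra, −0.169 at Socs1, 0.131 at Egr1 and −0.0368 at Ctla4, and the upstream deletion −8.69e-04 at Nkg7, 5.92e-04 at Tnf, −0.130 at S1pr1, −0.0106 at Il2rb and −0.231 at Slc2a1. Scaled by distance class, Socs1 had −0.0157 in the intron deletion and −0.0221 in the upstream deletion, which had −0.0223 at Nkg7, −9.40e-04 at S1pr1, −0.0261 at Cd3g, −0.0415 at Il2rb and −0.0212 at Slc2a1. In the upper part by count the intron deletion had 0.0484 at Egr1 and −0.0664 at Ctla4, scaled by bin coverage 0.0392 at Egr1, and over the gene span the upstream deletion had 0.00817 at Tnf.

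Leaving out 1 library at a time gave ranges that include the reversed values. With IL-2, Il2ra ran from −0.0587 to 0.267, and the adjusted p of the activation genes from 0.820 to 0.962. In the intron deletion the ranges were −0.0616 to 0.159 at Socs1, −0.309 to 0.00621 at Tnf, −0.437 to 0.0456 at Il7r, −0.0847 to 0.324 at Cd3d, −0.0488 to 0.346 at Cd3g, −0.109 to 0.0611 at Egr1 and −0.874 to 0.225 at Slc7a5. In the upstream deletion they were −0.0266 to 0.231 at Cish, −0.0250 to 0.136 at Socs1, −0.0393 to 0.132 at Nkg7, −0.146 to 0.0874 at Tnf, −0.0715 to 0.206 at S1pr1, −0.0289 to 0.237 at Cd3d, −0.177 to 0.243 at Cd3g, −0.155 to 0.0860 at Ctla4, −0.0910 to 0.123 at Il2rb, −0.0905 to 0.177 at Slc2a1 and −0.474 to 0.230 at Slc7a5.

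No paired analysis was possible because the labels give no replicate numbers to pair by; the genotype term already compares control and IL-2 libraries within each genotype. Depth limits these results, since a pair under 20 contacts is not listed.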

Other observations

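In this part, all tests were chosen after the result was seen. Besides the genes already named, the 58 gene ends whose IL-2 response differed in the intron deletion included the following, which were singled out after their values were seen. Contacts fell in WT and the upstream deletion, and were close to their control values in the intron deletion, at Dgka, a kinase that removes diacylglycerol (−0.46, −0.72 and 0.01 in WT, the upstream deletion and the intron deletion; adjusted p of the difference 7.77e-06), Cdkn1b, the cell cycle inhibitor p27 (−0.33, −0.68 and 0.01; adjusted p = 1.48e-05) and Zc3h12d, an RNA-degrading protein of lymphocytes (−0.51, −0.66 and 0.06; adjusted p = 1.14e-06). They fell less in the intron deletion at Tnfaip3, an inhibitor of NF-kB signalling (−0.55, −0.65 and −0.14; adjusted p = 3.55e-05). Contacts rose in WT and the upstream deletion at Coro2a, an actin-binding protein (0.73, 0.78 and 0.00; adjusted p = 1.86e-05). The T cell receptor gene Cd3e (−0.21, −0.37 and 0.09; adjusted p = 0.00689) and the lymphotoxin gene Ltb (−0.29, −0.33 and 0.01; adjusted p = 0.00476) also passed.

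Coverage of 53 shared bins at 24 loci on 14 chromosomes differed by more than log2 1.5 between the intron deletion and WT in both treatments, against 1 bin for the upstream deletion. The 12 lower bins lay at 6 loci, at or near Apobec3, Ly6e, Cdk17, Lasp1, Tnfaip8 and Smg1. Inside Apobec3 the bin at 15:79900001 held 5842 and 5440 reads in WT and 200 and 283 in the intron deletion (−4.32 and −4.05), and the bin at 15:74935001 near Ly6e held 6133 and 7330 in WT and 997 and 1429 in the intron deletion (−2.08 and −2.15). The 41 higher bins lay at 18 loci, among them the bin at 19:59350001 near Pdzd8, with 101 and 122 reads in WT, 825 and 1252 in the intron deletion (3.58 and 3.57) and 453 and 457 in the upstream deletion (2.41 and 2.35), and bins inside Kat2b, a histone acetyltransferase gene, and Fam240a.

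For these bins, WT libraries set apart from both deletion genotypes were argued against where the intron deletion was lower. Over loci the median upstream deletion difference was 0.0252 of that of the intron deletion (bootstrap 95% interval −0.00522 to 0.102). Where it was higher the median was 0.214 (0.134 to 0.305), which leaves a part played by the WT libraries open. A strain variant carried in blocks also stays open: 25% of the loci had another within 100 kb to 5 Mb, against a median of 16.7% and a highest value of 54.2% in 1000 random draws, and a variant at a lone locus needs no neighbour. As background, the C57BL/6 form of Apobec3 carries a retroviral insertion that other strains lack, and all labels give C57BL/6J. No biological explanation was tested for these bins.

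Many loops differed between the intron deletion and WT (3166 of 28033), 3138 of them in the same direction in both treatments. Of loops with a mean of at least 50 contacts 18.9% were called, against 11.3% over all loops, so the differences were not confined to low counts. This cannot decide on depth and the minimum of 20 contacts as their cause, since higher counts give more power. The share also rose for IL-2 (3.30% to 7.69%) and the upstream deletion (0.0785% to 0.220%). Against counting error in single libraries, the differences in control and in IL-2 libraries, which share no library, correlated at r = 0.605. That value is over loops with a mean of at least 50 contacts, which are not independent replicates. Against a missing IL-2 response in the control cells, the difference in control libraries correlated with the upstream deletion's response at r = −0.0373. Differences between the animals or cultures behind the genotypes were not tested and stay open beside the deletion itself, since each genotype may come from 1 culture.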
